A study of Mus musculus with 12 samples.

How the data were processed

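RNA from dorsal root ganglia of mice injected with AAV-shGpr151 was sequenced as input and as CSDE1 immunoprecipitate, with and without sciatic nerve injury. Per the labels' protocols, immunoprecipitated RNA was purified on silica columns and libraries were made with a nanopore cDNA-PCR barcoding kit. The submitters' processing notes name minimap2 and Salmon, and the genome builds GRCm39 and mm39. Versions, settings and the gene annotation are not given in the sources used here.

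One table of the whole series was examined. Per the file headers, the authors deposited 1 column of Ensembl gene identifiers and 12 columns of values. The values are whole numbers per gene, and how the authors made them from the aligner's or quantifier's output is not given in the sources used here. These 12 columns were not used in any result. A column was to be used only where its name matched the labels of 1 sample, or of 1 group. The assay, the word control or shGpr151, and the replicate number in each column name were compared with the sample titles. This left 2 matching samples for each of the 6 hairpin columns and 0 for each of the 6 control columns. The word control was compared with the hairpin that opens each title, and the headers do not say what it stands for.

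Before the data were examined, a count model with 1 term per group was chosen for the 5 comparisons, together with tests of 30 gene lists. None was run. The planned rule for named genes covered Gpr151, Csde1, Atf3, Sprr1a and Gap43 in every comparison and added the genes with the largest changes; with no comparison made, only these 5 fixed names were looked up, and 4 of them had a row. Gene identifiers were matched to symbols by exact Ensembl identifier, ignoring the version suffix, and 1086 of the 15596 identifiers had no match. Symbols in the lists were brought up to date through the older symbols in the same reference where it gave any. Matching was done in Python 3.11.15 with pandas 2.3.3.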

Results

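The study concerned dorsal root ganglia, the clusters of sensory neuron cell bodies whose peripheral axons run in nerves such as the sciatic nerve. The 12 samples described here came from mice injected with an adeno-associated virus (AAV) carrying a short hairpin RNA against Gpr151, which encodes an orphan G-protein-coupled receptor. RNA was sequenced from ganglion lysate (input) and from material immunoprecipitated from such lysate with an antibody to CSDE1, a cytoplasmic RNA-binding protein with cold shock domains. The labels divide the samples into 4 groups of 3, namely input from ganglia labelled uninjured, input from ganglia labelled injured, and immunoprecipitate from each of these. The injury was to the sciatic nerve. The labels do not say whether the 3 samples of a group came from separate animals.

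This design implies 5 comparisons. Immunoprecipitate against input, in uninjured and in injured ganglia, addresses which transcripts were recovered with the CSDE1 antibody. By the labels, no group is an immunoprecipitate made with another antibody. Binding to CSDE1 could therefore not be told apart from nonspecific recovery. Injured against uninjured input addresses the response of total RNA to nerve injury, and the same comparison in the immunoprecipitate addresses the change in recovered RNA. The interaction of injury and immunoprecipitation addresses whether recovery with the CSDE1 antibody differed after injury beyond the change in the input. None of the 5 comparisons could be made, because no column of values in the table used here could be assigned to one of the 4 groups.

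The table has 12 columns of values, 6 named for a control and 6 named for the Gpr151 hairpin. Within each 6, 3 columns are named for the immunoprecipitate and 3 for the input. No column name says injured or uninjured, and the names do not say what control stands for. Each of the 6 hairpin columns therefore matched 2 samples equally well, 1 uninjured and 1 injured, which belong to different groups. The word control was read as a condition without the hairpin. On that reading, the 6 control columns matched 0 of the 12 samples, all labelled with the hairpin virus. Injury state was not inferred from the expression of injury-responsive genes, since groups chosen in this way would carry the outcome under study into their own definition. It was not inferred from column order or from the number of columns either, because neither is stated to follow the groups. No expression level, fold change, error or test is reported for any gene, and the sequencing depth of the 12 samples is likewise not reported.

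The gene identifiers, which belong to no sample, were the only part of the table used in a result. The table has 15596 rows, each with a distinct Ensembl mouse gene identifier, and 14510 of these (93.0%) were matched to a gene symbol. A row shows that a gene was carried in the table and gives neither its level nor the samples in which it was seen. Csde1, the gene of the immunoprecipitated protein (ENSMUSG00000068823), has a row. So do Atf3 (ENSMUSG00000026628), a transcription factor gene used as a marker of axotomised neurons, Sprr1a (ENSMUSG00000050359) and Gap43 (ENSMUSG00000047261), both associated with axon growth. Gpr151, the target of the hairpin (ENSMUSG00000042816), was also looked up, and its identifier matched none of the 15596 rows used here. The lack of a matching row was not read as a low level, since how the rows were chosen is not given in the sources used here. The knockdown was not checked, since no column of values was used in any result. With no row matched to Gpr151, these columns would also have given no value for it under any assignment to groups. By their labels, the 12 samples also include no group without the hairpin against which the knockdown could have been checked.

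Among gene groups fixed before the data were examined, rows were matched for 39 of 44 genes associated with the neuronal injury response and for 27 of 29 genes of nociceptor identity. All 23 genes of large-fibre neurons and all 24 pan-neuronal genes were matched. For cells other than neurons, rows were matched for 17 of 18 satellite glial genes, 18 of 18 myelinating Schwann cell genes, 23 of 23 macrophage genes, 15 of 15 endothelial genes and 20 of 20 fibroblast genes. Coverage was lower for genes of lymphocytes and neutrophils, with 13 of 18, for genes of repair Schwann cells, with 10 of 12, and for genes of spinal cord neurons and glia, with 5 of 12. Of 14 genes listed as reported CSDE1 targets, 13 were matched. Coverage of each remaining list lay between 87.0% (genes of the interferon response, 20 of 23) and 100%. These counts describe which genes the table covers and were not compared with any background.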

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

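No comparison between groups was made, so none of the settings chosen before the data were examined (other scaling factors, other filters on low counts, other tests, fits restricted to the groups compared and leaving out each library) was run. The one setting tried was chosen after seeing the data. Of the 15596 gene identifiers, 14510 were matched to a symbol, and 13836 when the symbol also had to be in the RefSeq gene table of the mouse assembly GRCm38.p6. No paired analysis was possible because the columns, although numbered, give no injury state and could not be assigned to the groups compared.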
